A study of Mus musculus with 8 samples.

How the data were processed

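The study compared CTL-EN cells, a mouse T cell line, that carried the human GM-CSF receptor beta common chain as the wild type or with a serine changed to glycine (Ser585Gly). Per the labels, cells were kept for 12 h without factor in medium with 0.5% serum (0 h) and then received human GM-CSF at 50 ng/mL for 12 h (12 h). RNA was extracted with Trizol, labelled with a first-strand kit and hybridised to 2-colour spotted oligonucleotide arrays. The 8 arrays formed a square with 4 edges, which were Ser585Gly against wild type at 0 h, the same comparison at 12 h, 12 h against 0 h in wild type, and 12 h against 0 h in Ser585Gly. Each edge was hybridised in 2 dye orientations; replicate 1 had Ser585Gly or the 12 h RNA in Cy5, and replicate 2 had it in Cy3. The labels name no separate cultures or extracts, and the series notes say that the RNA also served a companion series, so each dye swap was read as a technical repeat of 1 comparison. The p-values of single probes (limma) therefore measure the spread between hybridisations only.

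The scanner values per array were in intensity units per the file headers, with a foreground and a local background for each dye. Each array had 23040 spots in 48 blocks of 24 rows and 20 columns. The steps that made these intensities are not given in the sources used here. The deposited value table held log2 ratios of Cy5 over Cy3, not turned for dye orientation. The submitters' notes name limma without a version or steps. The median absolute log2 ratio was 0.140 on all 8 arrays, so that the authors had scaled the arrays to each other. Background subtraction, print-tip loess and scaling of the scanner values came closest to that table, but the exact method is not given in the sources used here. Median foreground intensity was 631 to 946 in Cy5 and 795 to 1105 in Cy3, at 39.2 to 330 times the local background in Cy5 and 6.38 to 16.0 times in Cy3. Between 102 and 178 spots per array were near the top of the scanner range in either dye. The number of arrays limits the precision.

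The scanner files carry no probe names, so probes were placed on spots by setting the deposited log2 ratios of all 8 arrays against the scanner values. Of 1012 control probes with a coded position, 94.1% had that spot as their nearest by values. In all, 21766 non-control probes were placed, 77 of them after a shift that followed mutual matches. In addition 16 probes were dropped for sharing a spot, and 1274 spots were left for controls and unplaced probes. The placed spot was the nearest by values for 90.4% of probes, against 0.023% after shuffling. The correlation with the deposited values ran from 0.948 to 0.996 per array.

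The deposited order of probe names follows a print with 48 pins, whereas empty wells, buffer wells and abundant gene families fell on spots of matching brightness in a print order with 24 pins and not in the deposited order. Positive control wells were bright in both. All gene names used here rest on that recovered order. It was chosen after the data were seen, from the brightness of controls and of abundant and silent gene families. Fold changes of probe pairs of 1 gene were not used to choose it. Wells named empty on gene plates (244) had a median brightness percentile of 47.2 in the deposited order and 1.33 in the recovered order, and Gapdh control probes (152) had 88.4 and 97.4. In the other 24-pin orders tried, empty wells had 1.66 and 1.83 and Gapdh probes 97.5 and 97.4. These controls therefore bear on the number of pins and do not separate the 24-pin orders. Abundant families had 94.6 in the recovered order and 84.3 and 78.3 in the other 24-pin orders. Abundant and silent families could be compared plate by plate on 37 plates, which held 69.1% of named probes. The share of pairs with the abundant gene brighter was above 0.6 on 36 of these plates in the recovered order. On the remaining plate it was 0.333, against 0.458 in the deposited order. Other plates held too few such genes for this check. Symbols were updated through the gene tables supplied, by gene identifier for 15964 placed probes and by accession for 6, while 665 kept the symbol of the annotation. This gave 1 symbol for 16635 probes (15090 distinct symbols); 137 probes had several symbols and 4994 had none. The human receptor chain has no probe here, so the introduced gene itself was not measured. Spp1 and Csf2rb, which were due to be named in each comparison, were not analysed here.

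The choices in this paragraph were made before the data were examined. Background was corrected by normexp with an offset of 50, and each array was normalised by loess with a span of 0.3 and no weight on control spots. limma 3.58.1 in R 4.3.3 fitted all 8 arrays together with terms for mutation, time, their interaction and dye, with 4 residual and 4.35 prior degrees of freedom. Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over the 21766 probes, with an adjusted p under 0.05 as the threshold. Because dye swaps are technical, each count is also given with every dye-swap pair averaged to 1 value. In each contrast, genes were named by rule. The rule took the 10 largest increases and 10 largest decreases among probes past the threshold with the same direction on both direct arrays and 1 symbol. It also took up to 4 members past the threshold of each gene list by smallest p, and a short list of 13 measured GM-CSF-related genes whether they passed or not. The report gives these 13 in each contrast and, of the others, the few with the clearest known function.

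The 26 gene lists, written beforehand, were cell cycle and DNA replication, JAK-STAT cytokine targets, immediate-early and ERK targets, anti-apoptotic genes, pro-apoptotic genes, FoxO targets and quiescence, p53 targets, NF-kB targets, ribosome biogenesis and nucleolus, amino acid response and integrated stress response, cholesterol and fatty acid synthesis, glycolysis and hypoxia response, oxidative phosphorylation, cytosolic ribosomal proteins, proteasome, heat shock and chaperones, autophagy and lysosome, interferon response, T cell identity, T cell effector and cytokines, adhesion with osteopontin and integrins, and markers of myeloid cells, B cells, erythroid cells and megakaryocytes, mast cells and basophils, and fibroblasts and stroma. Each was tested with camera in limma on the brightest probe per gene, with a preset correlation of 0.01, two-sided, and the 130 tests over 5 contrasts were adjusted together by Benjamini-Hochberg. With the preset, camera compares the members of a list with all other genes. Its p-values therefore measure the spread across genes, not between hybridisations or cultures. The tests were repeated with a correlation estimated for each list. That form of the test also uses only the 4 residual degrees of freedom, so p rises even for lists without correlation. For the proteasome over time in wild type the estimate was −0.00099, under the preset, and p went from 3.6e-06 to 0.0062 (camera). A call lost in this form therefore does not show by itself that the members are correlated. Over the lists the estimate ran from −0.0579 (erythroid and megakaryocyte markers) to 0.206 (glycolysis and hypoxia). It was 0.134 for the cell cycle and 0.0714 for ribosome biogenesis. Where the estimate is above the preset, correlation raises p as well.

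The fit was tested on simulated data with 200 changed probes among 21766 per comparison. A simulated log2 change of 1 was recovered for 94% to 98% of probes and a change of 0.5 for 10% to 22%. Between 8 and 16 of the 162 to 174 probes past the threshold were false. Data with no change gave 4 probes past the threshold over 5 contrasts and 0 of 130 list tests. The noise was drawn for each probe on its own, so list members were uncorrelated in the simulation. In the data the estimated correlation was 0.206 for glycolysis and hypoxia genes, so the simulation does not show how often correlated lists pass. A list of 31 genes shifted by 0.3 had an adjusted p of 3.93e-26 by camera and no other list passed in that contrast.

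Alternatives covered background correction, normalisation within and between arrays, the dye term, the handling of dye swaps, direct arrays alone, dim probes, the variance prior, the deposited value table, each array left out in turn, the correlation between genes and the choice of probe per gene. The remaining tools were Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.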

Results

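The data were 8 2-colour arrays from 2 cell populations at 2 times, with 2 dye orientations for each edge of the square. Values are log2 ratios with the standard error of the limma fit over all 8 arrays. Gene names rest on the print order recovered from the spots. Dye-swap arrays, turned to the same direction, correlated across probes at 0.515 for time in wild type, 0.509 for time in Ser585Gly, 0.124 for the mutation at 0 h and 0.218 for the mutation at 12 h.

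The first comparison asked how factor-deprived cells with the wild-type receptor chain differed after 12 h with GM-CSF. No array held cells kept for those 12 h without GM-CSF, so effects of GM-CSF and of time in culture cannot be told apart. The GM-CSF response below means the change from 0 h to 12 h. Pim2, a serine/threonine kinase that supports survival, rose by 2.72 ± 0.11 (SE, 8 arrays). Cish, a feedback inhibitor of cytokine receptors, rose by 2.06 ± 0.11. Il2ra, the alpha chain of the interleukin-2 receptor, rose by 1.81 ± 0.14 on the brightest of 4 probes, all past the threshold, and Bcl2l1, which encodes Bcl-xL, by 1.14 ± 0.10. Irf7, an interferon regulatory factor, fell by 2.75 ± 0.16, and Mxd4, an antagonist of Myc at Max, fell by 2.60 ± 0.20. The adjusted p was 6.99e-05 for Pim2 and 0.00012 for Cish and Irf7 (limma, Benjamini-Hochberg). Other large increases were in Tnfrsf11b, which encodes the decoy receptor osteoprotegerin (2.68), Il24, an interleukin-10 family cytokine (2.65), Mycn, a Myc family transcription factor (2.31), and Lta, which encodes lymphotoxin alpha (2.12). Other large decreases were in Bnip3, a mitochondrial protein of mitophagy and hypoxia (−2.28), Trp53inp1, a p53-induced stress protein (−2.20), and Pik3ip1, an inhibitor of phosphoinositide 3-kinase (−2.21).

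In wild type 5 gene lists passed as higher at 12 h (camera, Benjamini-Hochberg adjusted p). Of 36 genes of the amino acid response, 22 rose and 1 fell, or 26 and 1 adjusted over the list alone (adjusted p = 1.73e-14; adjusted p = 0.0677 with an estimated correlation). Slc7a5 (1.98) and Slc3a2 (1.64), the subunits of an amino acid transporter, and the serine synthesis enzymes Psat1 (1.38) and Phgdh (1.33) were among them. Of 33 ribosome biogenesis genes, 19 rose and 0 fell, or 20 and 0 adjusted over the list alone (adjusted p = 1.40e-09; adjusted p = 0.143 with an estimated correlation), among them Odc1, the enzyme that starts polyamine synthesis (1.91), and Nop56, a nucleolar protein (0.89). JAK-STAT targets rose in 8 and fell in 1 of 20, or 11 and 3 adjusted over the list alone (adjusted p = 0.000113; adjusted p = 0.183 with an estimated correlation). Proteasome genes rose in 4 of 31 and fell in 0, the same adjusted over the list alone (adjusted p = 3.34e-05; adjusted p = 0.0727 with an estimated correlation). Cell cycle genes rose in 8 and fell in 2 of 48, or 12 and 4 adjusted over the list alone (adjusted p = 0.0176; adjusted p = 0.603 with an estimated correlation). That call was lost without replicate 1 of 12 h against 0 h in wild type (adjusted p = 0.116).

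Another 4 lists passed as lower in wild type (camera). FoxO targets fell in 11 and rose in 1 of 29, or 19 and 1 adjusted over the list alone (adjusted p = 5.60e-10; adjusted p = 0.0677 with an estimated correlation), with Cdkn1b, the cell cycle inhibitor p27, at −1.29 ± 0.09 and Btg2, an antiproliferative gene, at −1.82. Glycolysis and hypoxia genes fell in 10 and rose in 1 of 27, or 11 and 2 adjusted over the list alone (adjusted p = 6.37e-05; adjusted p = 0.391 with an estimated correlation), with the glycolytic enzyme Pgk1 at −1.40. Autophagy and lysosome genes fell in 6 and rose in 0 of 30, or 7 and 1 adjusted over the list alone (adjusted p = 0.00609; adjusted p = 0.160 with an estimated correlation), with Lamp2, a lysosomal membrane protein, at −0.91. Ribosomal protein genes had a median of −0.13 with 1 higher and 1 lower of 58, or 1 and 0 adjusted over the list alone (adjusted p = 0.0112; adjusted p = 0.160 with an estimated correlation). That last call was also lost with the deposited value table, print-tip loess, a random block and a trended prior (adjusted p = 0.188, 0.0515, 0.0668 and 0.0746).

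The other lists did not pass in wild type. Apoptosis lists were mixed. Pro-apoptotic genes rose in 5 and fell in 6 of 27 (adjusted p = 0.999; median 0.04 and mean −0.12), with Pdcd4, a translation inhibitor, at −1.66 and the BH3-only gene Bmf at −1.06. Anti-apoptotic genes rose in 3 and fell in 0 of 15 (adjusted p = 0.417), with Bcl2 at 0.92. Immediate-early and ERK targets rose in 5 and fell in 2 of 26 (adjusted p = 0.254), with Dusp6, a phosphatase of ERK, at 1.48 and Egr1 at −0.15 (adjusted p = 0.773, limma). The adjusted p was 0.171 for NF-kB targets, 0.977 for p53 targets (median 0.04 and mean −0.14), 0.254 for cholesterol synthesis and 0.110 for oxidative phosphorylation. It was 0.182 for chaperones, 0.435 for the interferon response, 0.172 for T cell identity, 0.254 for T cell effectors and 0.183 for adhesion. For cell type markers it was 0.951 for myeloid cells, 0.828 for B cells, 0.963 for erythroid cells and 0.672 for both mast cells and fibroblasts. Among the receptor and survival genes named in each comparison, Pim1, a kinase related to Pim2, rose by 0.96 and Ccnd2, a D-type cyclin, by 0.73; Ccnd2 lost the call without replicates 1 or 2 of 12 h against 0 h in wild type (adjusted p = 0.0567 and 0.0658). Bcl2l11, which encodes the BH3-only protein Bim, was at −0.51 (adjusted p = 0.0171). Its call was lost with pairs averaged (adjusted p = 0.0626), without replicates 1 or 2 of that edge (0.0739 and 0.202) and without replicate 1 of the edge in Ser585Gly (0.0582). Myc was at 0.27 (adjusted p = 0.215), Socs2 at 0.32 (0.123), Mcl1 at −0.22 (0.223), Csf2ra at 0.03 (0.937) and Csf2rb2 at −0.24 (0.372). None of these 5 passed, and Csf2rb2 was too dim to judge, at brightness percentile 9.82.

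In total 2062 probes passed in wild type (limma, Benjamini-Hochberg), 1184 higher and 878 lower at 12 h, and 154 of these were at least 2-fold higher and 104 at least 2-fold lower. The count was 1062 with dye-swap pairs averaged. It was 411 without replicate 2 and 610 without replicate 1 of 12 h against 0 h in wild type, and 1059 without replicate 1 of that edge in Ser585Gly. It was 1368 without replicate 2 and 3303 without replicate 1 of the mutation edge at 0 h, and 1323 without replicate 2 of the mutation edge at 12 h.

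The second comparison asked the same of cells with the Ser585Gly chain. Tnfrsf11b rose by 2.68 ± 0.15, Mycn by 2.40 ± 0.13, Pim2 by 2.17 ± 0.11 and Cish by 2.06 ± 0.11 (adjusted p = 0.000148 for each, limma). Il2ra rose by 1.92 ± 0.14 on the same probe, Bcl2l1 by 1.05 and Lta by 2.10. Irf7 fell by 2.5 ± 0.16, and Sat1, the enzyme that starts polyamine breakdown, fell by 1.96 ± 0.11. Cdc6, which helps load the replicative helicase (1.38), and Mcm2, a subunit of that helicase (0.98), rose. Myc, a driver of growth genes, was at 0.67 (adjusted p = 0.00974). Bcl2, an inhibitor of apoptosis, rose by 0.77, and Socs2, a feedback inhibitor, by 0.61. Without replicate 1 of 12 h against 0 h in Ser585Gly these 3 lost the call (adjusted p = 0.159 for Myc, 0.0716 for Bcl2 and 0.180 for Socs2), and without replicate 2 Myc (0.0671) and Socs2 (0.0538) did. Pim1 was at 0.70 (adjusted p = 0.134 without replicate 1) and Ccnd2 at 0.66 (0.0994 and 0.0798 without replicates 1 and 2). Egr1 was at 0.04 (adjusted p = 0.950), Csf2ra at 0.12 (0.684), Mcl1 at −0.25 (0.175), Bcl2l11 at −0.29 (0.113) and Csf2rb2 at −0.22 (0.421), and none of these 5 passed.

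In Ser585Gly 6 lists passed as higher at 12 h (camera). Ribosome biogenesis genes rose in 21 and fell in 0 of 33, or 25 and 1 adjusted over the list alone (adjusted p = 3.72e-14; adjusted p = 0.0752 with an estimated correlation), including Polr1b, a subunit of RNA polymerase I (1.58), and Nop56 (1.35). Amino acid response genes rose in 19 and fell in 2 of 36, or 23 and 2 adjusted over the list alone (adjusted p = 9.66e-11; adjusted p = 0.0677 with an estimated correlation), including Slc7a5 (1.99) and Lars, a leucyl-tRNA synthetase (1.04). Cell cycle genes rose in 16 and fell in 4 of 48, or 20 and 7 adjusted over the list alone (adjusted p = 0.000532; adjusted p = 0.446 with an estimated correlation). JAK-STAT targets rose in 10 and fell in 2 of 20, the same adjusted over the list alone (adjusted p = 0.000732; adjusted p = 0.231 with an estimated correlation). Proteasome genes rose in 7 and fell in 0 of 31, or 13 and 0 adjusted over the list alone (adjusted p = 6.01e-06; adjusted p = 0.0677 with an estimated correlation). Chaperones rose in 6 and fell in 0 of 27, or 9 and 0 adjusted over the list alone (adjusted p = 0.00638; adjusted p = 0.355 with an estimated correlation), including the mitochondrial chaperone Hspd1 (1.12).

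FoxO targets fell in 11 and rose in 1 of 29 in Ser585Gly, or 21 and 1 adjusted over the list alone (adjusted p = 3.48e-09; adjusted p = 0.0677 with an estimated correlation), with Cdkn1b at −1.60. Glycolysis and hypoxia genes fell in 9 and rose in 0 of 27, or 12 and 0 adjusted over the list alone (adjusted p = 8.55e-05; adjusted p = 0.399 with an estimated correlation), with the glycolytic enzyme Tpi1 at −0.97. Autophagy and lysosome genes fell in 6 and rose in 1 of 30, or 9 and 1 adjusted over the list alone (adjusted p = 0.00556; adjusted p = 0.160 with an estimated correlation). The lists that did not pass had adjusted p = 0.694 for immediate-early and ERK targets, 0.218 for anti-apoptotic genes, 0.965 for pro-apoptotic genes, 0.325 for p53 targets, 0.394 for NF-kB targets and 0.173 for cholesterol synthesis. It was 0.636 for oxidative phosphorylation, 0.132 for ribosomal proteins, 0.977 for the interferon response, 0.192 for T cell identity, 0.848 for T cell effectors and 0.427 for adhesion. For cell type markers the adjusted p was 0.828 for myeloid cells, 0.888 for B cells, 0.977 for erythroid cells, 0.984 for mast cells and 0.824 for fibroblasts.

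In total 2273 probes passed in Ser585Gly, 1246 higher and 1027 lower, which is 54.8% higher. With median centring in place of loess 64.9% were higher. Of the passing probes, 169 were at least 2-fold higher and 73 at least 2-fold lower. The count was 1335 with dye-swap pairs averaged. It was 276 without replicate 1 and 920 without replicate 2 of 12 h against 0 h in Ser585Gly, and 1447 without replicate 2 of that edge in wild type. It was 3429 without replicate 1 of the mutation edge at 0 h, and 1515 without replicate 2 of the mutation edge at 12 h.

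The GM-CSF responses of the 2 populations were alike across genes. The direct log2 ratios of 21766 probes had a Pearson correlation of 0.721 and a Spearman correlation of 0.622, against −0.0193 to 0.0159 for Pearson in 20 simulated data sets with no effect. This is a correlation across probes, which are not independent replicates. Probes that passed in both populations numbered 752 higher and 591 lower. In addition 1 probe higher in wild type and 1 lower in wild type went the other way in Ser585Gly. The joint fit lets the 2 estimates share arrays. From direct arrays alone, which are not shared, 345 probes were higher in both, against 15.7 for independent sets, and 222 lower, against 8.15, with 0 in opposite directions (limma). This count was chosen after the first was seen. Both calls still share 1 estimate of spread per probe, which raises the overlap in either direction, so the value for independent sets is a low reference.

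**Figure D1:**
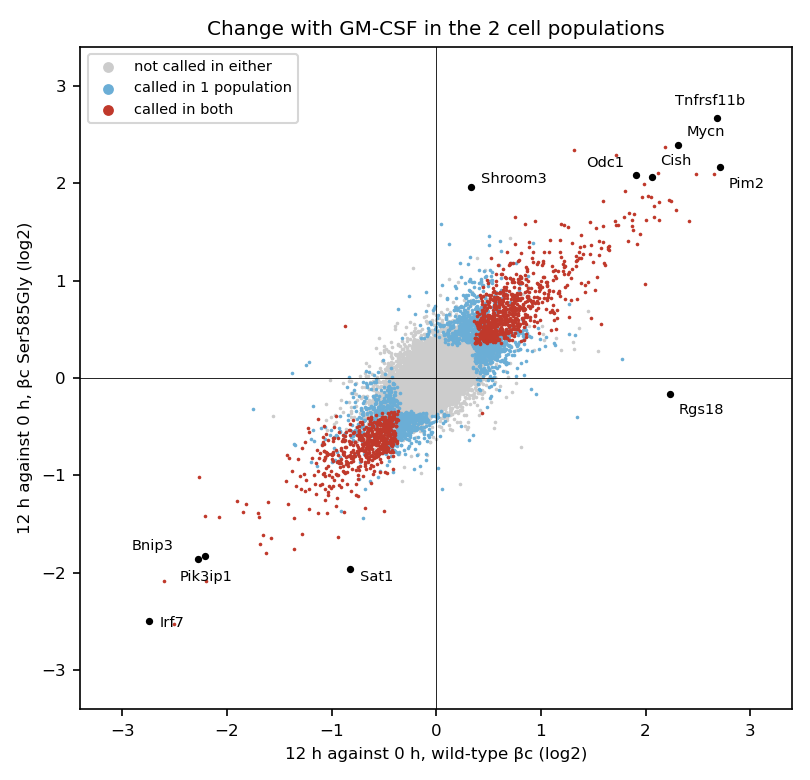
Each point is a probe, with its log2 ratio of 12 h over 0 h in wild type on the horizontal axis and in Ser585Gly on the vertical axis. Named genes sit in the upper right (Tnfrsf11b, 2.68 in both) and lower left (Irf7, −2.75 and −2.5).

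**Figure D2:**
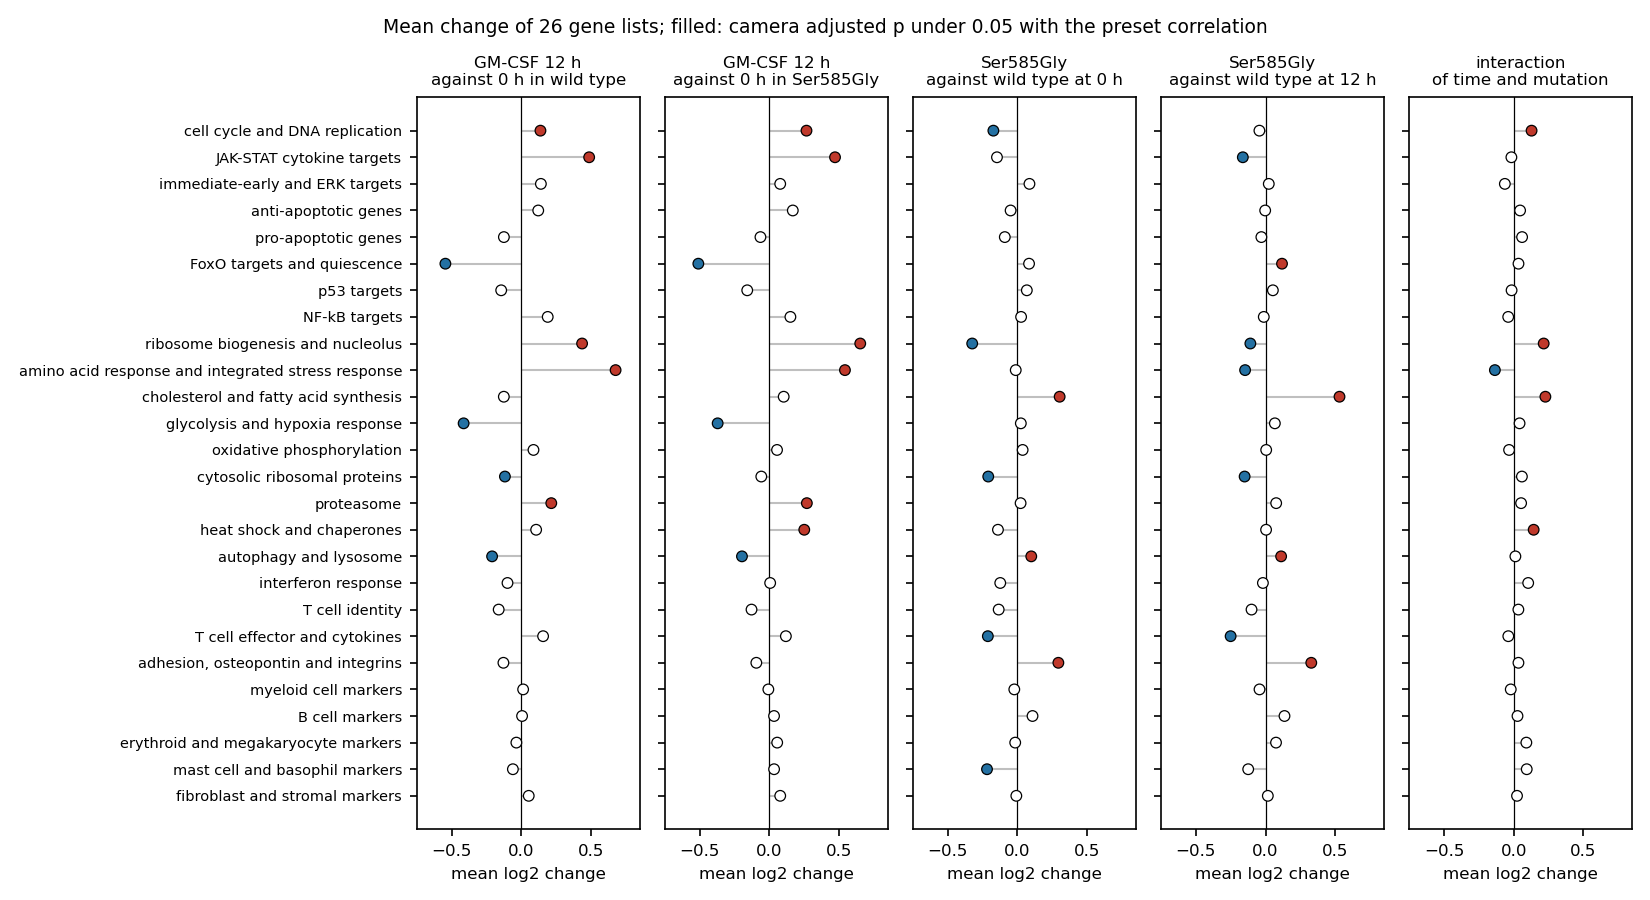
Each point is the mean log2 ratio of the members of a gene list, by contrast, with the log2 ratio on the horizontal axis and the 26 lists on the vertical axis. Filled points mark lists with a camera adjusted p under 0.05, such as cholesterol and fatty acid synthesis, with a mean of 0.23 for the interaction.

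The third comparison asked how Ser585Gly cells differed from wild type before GM-CSF. H2-Ab1, a beta chain of MHC class II, was higher by 1.64 ± 0.10 (adjusted p = 0.000317), Cd74, the invariant chain, by 1.41 ± 0.11 (adjusted p = 0.000564), and H2-Eb1 by 1.35 ± 0.12 (adjusted p = 0.00105; limma). Lgals3, the lectin galectin-3, was higher by 1.89 ± 0.16, and Cd55, which protects cells from complement, by 1.64 ± 0.13 with 3 of 3 probes past the threshold. Irf8, an interferon regulatory factor of blood cell development, fell by 2.28 ± 0.09 relative to wild type. Trf, which encodes transferrin, was at −2.61 ± 0.17 with 4 of 4 probes past the threshold, and Ctsg, the granule protease cathepsin G, at −2.07 ± 0.17. Ptprc, the leukocyte phosphatase CD45, was at −1.59 ± 0.12, Tbx21, which encodes the T cell transcription factor T-bet, at −1.51 ± 0.10, and Myc at −1.18 ± 0.12. Cish was at −0.70 (adjusted p = 0.0166, 0.0542 with pairs averaged, 0.0750 and 0.0572 without replicates 1 and 2 of this edge, and 0.0623 without replicate 1 of time in Ser585Gly). Pim1 (−0.60, adjusted p = 0.0345) and Bcl2l1 (−0.51, 0.0345) were lower too, but not with pairs averaged (0.0687 and 0.0892). Both lost the call when any 1 array except replicate 2 of time in Ser585Gly was left out (adjusted p = 0.0559 to 0.125 and 0.0590 to 0.130). The other genes of that short list did not pass: Socs2 (−0.50, adjusted p = 0.0501), Bcl2 (−0.12, 0.529), Bcl2l11 (−0.28, 0.151), Mcl1 (0.12, 0.487), Ccnd2 (0.03, 0.887), Egr1 (−0.36, 0.415), Il2ra (−0.33, 0.199), Csf2ra (−0.19, 0.449) and Csf2rb2 (0.04, 0.903). Another of the 4 Il2ra probes passed (−0.52, adjusted p = 0.0486).

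Cholesterol and fatty acid synthesis genes were higher in Ser585Gly at 0 h in 10 of 28 and lower in 0, or 14 and 0 adjusted over the list alone (camera adjusted p = 1.18e-06; adjusted p = 0.0677 with an estimated correlation), with the sterol enzymes Msmo1 at 0.78 and Mvd at 0.76. Both lost the call without replicate 2 of the mutation edge at 0 h (adjusted p = 0.0662 and 0.0734). Adhesion genes were higher in 7 and lower in 1 of 26, or 9 and 1 adjusted over the list alone (adjusted p = 0.00268; adjusted p = 0.368 with an estimated correlation), including S100a4 (1.28) and Anxa2 (1.28), which bind calcium, and Vim, the intermediate filament vimentin (1.16). The call was lost without replicate 2 of the mutation edge at 0 h (adjusted p = 0.0679). Ribosome biogenesis genes were lower in 9 and higher in 0 of 33, or 18 and 1 adjusted over the list alone (adjusted p = 1.79e-07; adjusted p = 0.160 with an estimated correlation), including Polr1b (−0.87, adjusted p = 0.0764 without the same array). Ribosomal protein genes had a median of −0.16 with 1 lower and 0 higher of 58, the same adjusted over the list alone (adjusted p = 3.65e-05; adjusted p = 0.0677 with an estimated correlation).

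The 4 other lists that passed at 0 h depended on single arrays. Cell cycle genes were lower in 2 and higher in 2 of 48, or 10 and 4 adjusted over the list alone (adjusted p = 0.0264; adjusted p = 0.637 with an estimated correlation). The call was lost without replicate 1 of the mutation edge at 0 h (adjusted p = 0.0668), replicate 1 of that edge at 12 h (0.0586) or replicate 1 of time in Ser585Gly (0.0559). T cell effectors were lower in 6 and higher in 1 of 34, or 9 and 1 adjusted over the list alone (adjusted p = 0.0248; adjusted p = 0.354 with an estimated correlation). It was lost without replicate 1 of the mutation edge at 0 h (adjusted p = 0.252). The granzyme Gzmg was among them (−0.78, adjusted p = 0.0861 without replicate 2 of that edge). Autophagy and lysosome genes were higher in 1 and lower in 0 of 30, or 7 and 1 adjusted over the list alone (adjusted p = 0.0373; adjusted p = 0.231 with an estimated correlation). Their call was lost with pairs averaged (adjusted p = 0.0694), without replicate 2 of the mutation edge at 0 h (0.131), without replicate 1 of that edge at 12 h (0.0611) and without replicate 1 of time in wild type (0.0607). Mast cell and basophil markers were lower in 1 and higher in 0 of 13, or 2 and 0 adjusted over the list alone (adjusted p = 0.0442; adjusted p = 0.276 with an estimated correlation). This was lost with pairs averaged (adjusted p = 0.0778), without replicate 2 of the mutation edge at 0 h (0.240), without replicate 1 of time in wild type (0.0720) and without replicate 2 of time in Ser585Gly (0.0520).

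Myeloid markers at 0 h were higher in 2 and lower in 1 of 25 (adjusted p = 0.759), with Ctsg lower and Fcgr3, an Fc receptor, at 0.87. The call of Fcgr3 was lost without replicates 1 or 2 of the mutation edge at 0 h (adjusted p = 0.0765 and 0.0868), replicate 2 of time in wild type (0.0566) or replicate 1 of time in Ser585Gly (0.0657). B cell markers were higher in 4 and lower in 2 of 19 (adjusted p = 0.725), with Cd74 and H2-Ab1 among the higher and Ighm, the heavy chain of IgM, at −2.08 on 1 of 9 probes. The adjusted p was 0.201 for JAK-STAT targets, 0.171 for immediate-early and ERK targets, 0.999 for anti-apoptotic genes, 0.636 for pro-apoptotic genes, 0.386 for FoxO targets, 0.325 for p53 targets, 0.515 for NF-kB targets and 0.977 for the amino acid response. It was 0.427 for glycolysis and hypoxia, 0.231 for oxidative phosphorylation, 0.368 for the proteasome, 0.301 for chaperones, 0.718 for the interferon response, 0.380 for T cell identity, 0.977 for erythroid cells and 0.810 for fibroblasts.

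In total 887 probes passed between the populations at 0 h, 451 higher and 436 lower in Ser585Gly, with 52 at least 2-fold higher and 76 at least 2-fold lower. The share higher was 50.8%. It was 39.6% with dye-swap pairs averaged, 41.0% with median centring in place of loess and 42.6% to 51.6% with single arrays left out, so the direction of the balance depends on the method and the arrays. The count was 275 with dye-swap pairs averaged. Leaving out replicates 1 and 2 of the mutation edge at 0 h gave 324 and 108, of that edge at 12 h 472 and 366, and of time in wild type 526 and 272. Leaving out replicate 1 of time in Ser585Gly gave 253.

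**Figure D3:**
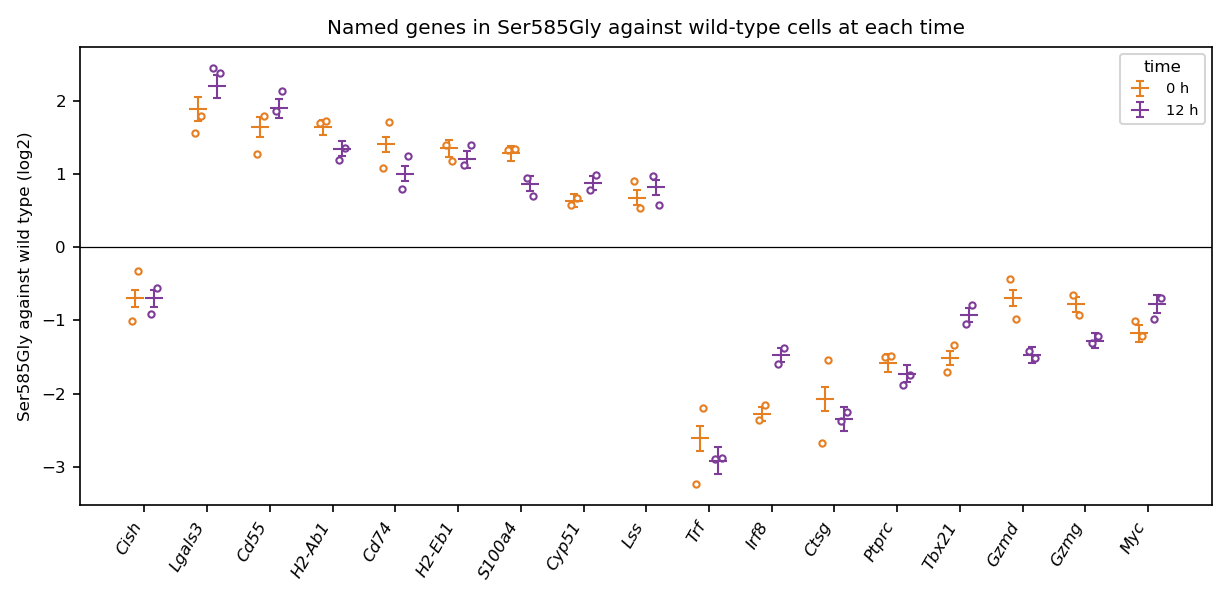
The vertical axis is the log2 ratio of Ser585Gly over wild type for the genes on the horizontal axis at 0 h and 12 h, with dashes and bars for the limma estimate ± SE and circles for the direct arrays. H2-Ab1, Cd74, H2-Eb1, Lgals3 and Cd55 lie above 0 and Irf8, Trf and Ctsg below 0 at both times, with Trf from a different probe at each time.

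The fourth comparison asked how the populations differed after 12 h of GM-CSF. Rgs18, a regulator of G-protein signalling, was lower in Ser585Gly (−3.70 ± 0.24, adjusted p = 0.000434) on its only probe. That probe was dim, at brightness percentile 19, under the median of 29.3 for silent gene families. Ctnnd2, which encodes a catenin of cell junctions, was higher (2.41 ± 0.11, adjusted p = 0.000202). Its probe was at brightness percentile 31.9, close to the median of silent gene families. Lgals3 (2.20 ± 0.16), Cd55 (1.90 ± 0.13), H2-Ab1 (1.35 ± 0.10) and H2-Eb1 (1.20) were higher at this time too. Trf (−2.92 ± 0.18, on another probe than at 0 h, with 3 of 4 past the threshold), Ptprc (−1.73 ± 0.12), Ctsg (−2.34) and Irf8 (−1.47 ± 0.09) were lower. The granzyme genes Gzmd (−1.48 ± 0.11, adjusted p = 0.000638), Gzmg (−1.28) and Gzme (−1.06), which are close in sequence, were lower in Ser585Gly (limma). Myc was at −0.77 (adjusted p = 0.0177, 0.0697 with pairs averaged, 0.161 and 0.113 without replicates 1 and 2 of this edge, and 0.0508 without replicate 1 of time in wild type). Pim1 was at −0.85 (adjusted p = 0.0122, 0.0416 with pairs averaged, and 0.114 and 0.165 without replicates 1 and 2 of this edge). Cish was at −0.70 (adjusted p = 0.0219 and 0.0797 with pairs averaged). It lost the call without replicates 1 or 2 of this edge (0.216 and 0.258), replicate 1 of time in wild type (0.0615), or replicates 1 or 2 of time in Ser585Gly (0.0702 and 0.0510). Bcl2l1 was at −0.60 (adjusted p = 0.0266 and 0.121 with pairs averaged), and lost the call when any 1 array except replicate 1 of the mutation edge at 0 h was left out (0.0515 to 0.236). The other genes of the short list did not pass: Bcl2 (−0.27, adjusted p = 0.341), Bcl2l11 (−0.06, 0.855), Mcl1 (0.10, 0.753), Socs2 (−0.21, 0.493), Ccnd2 (−0.04, 0.926), Egr1 (−0.17, 0.833), Il2ra (−0.22, 0.567), Csf2ra (−0.10, 0.835) and Csf2rb2 (0.05, 0.919). Another of the 4 Il2ra probes passed (−0.85, adjusted p = 0.0114).

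Cholesterol and fatty acid synthesis genes were higher in Ser585Gly at 12 h in 16 of 28 and lower in 0, or 18 and 0 adjusted over the list alone, with all 28 above 0 and a median of 0.61 (camera adjusted p = 8.39e-21; adjusted p = 0.0663 with an estimated correlation). Cyp51, which removes a methyl group from lanosterol, was at 0.88 (adjusted p = 0.00328, limma) and Sqle, the squalene epoxidase, at 0.82. Without replicate 2 of the mutation edge at 12 h they had adjusted p = 0.0694 and 0.0943, and Sqle had 0.0527 without replicate 1. Adhesion genes were higher in 7 and lower in 0 of 26, or 9 and 1 adjusted over the list alone (adjusted p = 3.34e-05; adjusted p = 0.239 with an estimated correlation), including Itgae, an integrin alpha chain of T cells in epithelia (1.76 on a dim probe, brightness percentile 20). T cell effectors were lower in 6 and higher in 0 of 34, or 8 and 0 adjusted over the list alone (adjusted p = 0.000732; adjusted p = 0.183 with an estimated correlation), the granzymes among them. Ribosomal protein genes had a median of −0.14 with 1 lower and 0 higher of 58, the same adjusted over the list alone (adjusted p = 6.37e-05; adjusted p = 0.0677 with an estimated correlation).

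The 5 other lists that passed at 12 h were lost without replicate 1 of the mutation edge at 12 h. Amino acid response genes were lower in 1 and higher in 0 of 36, or 5 and 0 adjusted over the list alone (adjusted p = 0.00214; adjusted p = 0.172 with an estimated correlation). They had adjusted p = 0.0684 without that array. Autophagy and lysosome genes were higher in 2 and lower in 0 of 30, or 5 and 0 adjusted over the list alone (adjusted p = 0.0193; adjusted p = 0.183 with an estimated correlation), and had adjusted p = 0.0611 without it. Ribosome biogenesis genes had a median of −0.13 with 0 of 33 past the threshold either way (limma), 0 also adjusted over the list alone (adjusted p = 0.0242; adjusted p = 0.447 with an estimated correlation). These had adjusted p = 0.411 without it. JAK-STAT targets were lower in 4 and higher in 1 of 20, or 6 and 1 adjusted over the list alone (adjusted p = 0.0248; adjusted p = 0.368 with an estimated correlation). Their test had adjusted p = 0.125 without it and 0.0597 without replicate 1 of the edge at 0 h. The JAK-STAT call was also lost with print-tip loess (camera adjusted p = 0.0884) and with the deposited value table (0.0863). FoxO targets were higher in 2 and lower in 1 of 29, or 6 and 2 adjusted over the list alone (adjusted p = 0.0374; adjusted p = 0.355 with an estimated correlation). Their adjusted p was 0.253 without it, 0.0636 without its dye swap, 0.0799 without replicate 2 of the edge at 0 h and 0.0534 without replicate 2 of time in wild type.

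B cell markers at 12 h were higher in 4 and lower in 0 of 19 (adjusted p = 0.654), and myeloid markers were higher in 2 and lower in 1 of 25 (adjusted p = 0.942). The adjusted p was 0.584 for the cell cycle, 0.888 for both immediate-early and NF-kB targets, 0.951 for anti-apoptotic genes and 0.849 for pro-apoptotic genes. It was 0.828 for both p53 targets and oxidative phosphorylation, 0.171 for glycolysis and hypoxia, 0.0535 for the proteasome and 0.620 for chaperones. It was 0.813 for the interferon response, 0.466 for T cell identity, 0.849 for erythroid cells, 0.135 for mast cells and 0.759 for fibroblasts.

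In total 373 probes passed at 12 h, 199 higher and 174 lower in Ser585Gly, with 58 at least 2-fold higher and 48 at least 2-fold lower. The share higher was 53.4%, but 44.8% and 48.1% without replicates 1 and 2 of the mutation edge at 12 h. The count was 151 with dye-swap pairs averaged. Leaving out replicates 1 and 2 of the mutation edge at 12 h gave 67 and 79, of that edge at 0 h 625 and 232, and of time in wild type 192 and 189. Leaving out replicate 1 of time in Ser585Gly gave 174.

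The last comparison asked whether the GM-CSF response itself differed between the populations. Rgs18 was at 2.24 in wild type and −0.16 in Ser585Gly, an interaction of −2.40 (adjusted p = 0.0363) on that dim probe, and Ctnnd2 was at 0.05 and 1.58 (interaction 1.53, adjusted p = 0.00692). Sat1 was at −0.83 and −1.96, an interaction of −1.13 (adjusted p = 0.0363; limma). The call was lost for Sat1 when any 1 of the 8 arrays was left out (adjusted p = 0.0686 to 0.327) and for Rgs18 when any except replicate 2 of time in Ser585Gly was (0.0662 to 0.327). Ctnnd2 lost it without replicates 1 or 2 of the mutation edge at 12 h (0.0752 and 0.0702), replicate 2 of time in wild type (0.0662) or replicate 1 of time in Ser585Gly (0.0657). In all 12 probes passed, 6 higher and 6 lower. The count was 0 with dye-swap pairs averaged (limma), where 1505 probes had an unadjusted p under 0.05, against 1525 over all arrays. Leaving out replicates 1 and 2 of the mutation edge at 0 h gave 5 and 3, of that edge at 12 h 0 and 0 (limma; 1060 and 1143 with an unadjusted p under 0.05). The counts were 5 and 0 for time in wild type (968 for the latter), and for time in Ser585Gly 0 and 5 (962 for the former).

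Among gene lists, the response of ribosome biogenesis genes was higher in Ser585Gly by a median of 0.17, with 27 of 33 above 0 (camera adjusted p = 6.78e-07, and 0.172 with an estimated correlation). This larger rise began from a lower level. The median of these genes in Ser585Gly against wild type was −0.34 at 0 h and still −0.13 at 12 h. Cholesterol and fatty acid synthesis genes had a median interaction of 0.24, with 24 of 28 above 0 (adjusted p = 8.07e-07; adjusted p = 0.0677 with an estimated correlation). Amino acid response genes had a median of −0.15 (adjusted p = 0.000732; adjusted p = 0.160 with an estimated correlation). Cell cycle genes (median 0.09, adjusted p = 0.0373; adjusted p = 0.652 with an estimated correlation) lost the call without replicate 1 of the mutation edge at 0 h (adjusted p = 0.0924), replicate 2 of that edge at 12 h (0.198), replicate 2 of time in wild type (0.0676) or replicate 1 of time in Ser585Gly (0.204). Chaperones (median 0.13, adjusted p = 0.0248; adjusted p = 0.410 with an estimated correlation) lost it without replicates 1 or 2 of the mutation edge at 12 h (adjusted p = 0.05005 and 0.0526), replicate 2 of time in wild type (0.120) or replicate 2 of time in Ser585Gly (0.0917). Both lists also lost the call with direct arrays alone (camera adjusted p = 0.237 for the cell cycle and 0.119 for chaperones). The same held for the deposited value table (0.0885 for both) and for probes at their nearest spot (0.272 and 0.121). The cell cycle call was lost without the dimmest probes (0.0542), and that of chaperones with print-tip loess (0.0951). The count of single members of these 5 lists that passed over all probes was 0 (limma), and adjusted over the list alone 3 ribosome biogenesis genes and 1 cholesterol gene were higher and 4 amino acid response genes lower. None of the 13 genes named in each comparison had an interaction that passed (limma). The values were 0.40 for Myc (adjusted p = 0.627), 0.29 for Socs2 (0.736), 0.22 for Bcl2l11 (0.756), 0.19 for Egr1 (0.873), 0.11 for Il2ra (0.867; −0.42 to 0.11 over 4 probes), 0.09 for Csf2ra (0.891) and 0.02 for Csf2rb2 (0.978). They were 0.00 for Cish (0.997), −0.02 for Mcl1 (0.963), −0.07 for Ccnd2 (0.897), −0.09 for Bcl2l1 (0.853), −0.15 for Bcl2 (0.799) and −0.26 for Pim1 (0.756).

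**Figure D4:**
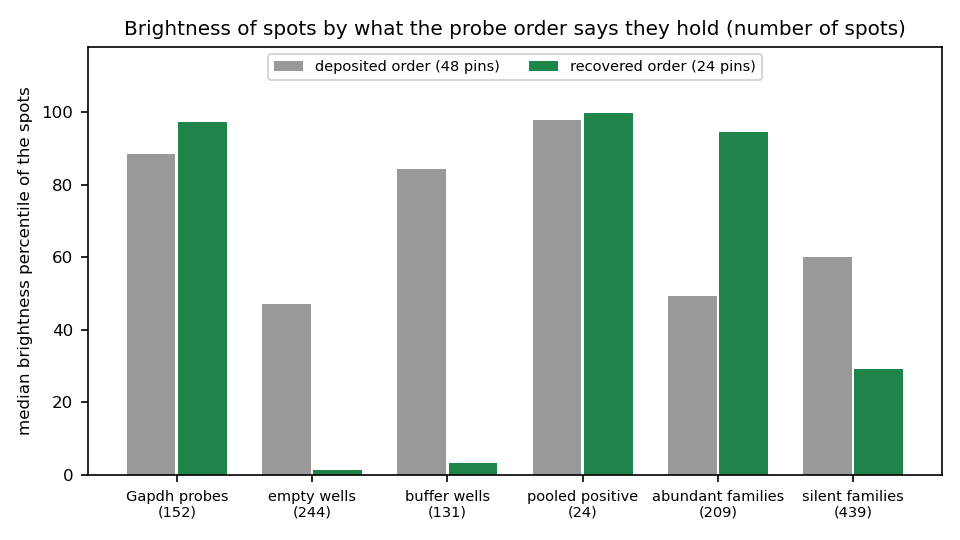
Bars show the median brightness percentile (vertical axis) of groups of spots (horizontal axis) in the deposited and the recovered print order. Empty wells are at 47.2 in the deposited order and 1.33 in the recovered order.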

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

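The test of dye bias in this part was chosen only after the result was seen, and the comparison with lists of matched brightness was written down before its outcome was seen.

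A difference between the GM-CSF responses of the 2 populations, tested as an interaction, drew attention to 12 probes (limma). The interaction was negative for Rgs18 (−2.40), Sat1 (−1.13), Xpnpep2, an aminopeptidase (−1.19), and Trim29, a tripartite motif protein (−1.02). The Rgs18 probe was at brightness percentile 19, under the median of silent gene families, and the Xpnpep2 probe at 29.9. The interaction was positive for Ctnnd2 (1.53), Shroom3, an actin-binding protein (1.63), Tln2, an integrin-linked talin (1.41), Ighm (1.43) and Gm8979 (0.95). The Ctnnd2 and Shroom3 probes were at brightness percentiles 31.9 and 36.6. Of 3 probes without a symbol, CGEN_MOUSE_EXT_3109391_1 was at 1.38, CGEN_MOUSE_EXT_3105177_1 at −1.74 and CGEN_MOUSE_EXT_3105178_1 at −1.12. The adjusted p ran from 0.00692 to 0.0363, and from 0.140 to 0.433 with dye-swap pairs averaged. Shroom3 was at 0.33 in wild type and 1.96 in Ser585Gly, and Trim29 at 1.57 and 0.55. The sign of the interaction does not give the size of the response. Sat1 fell in both populations, and more in Ser585Gly (−0.83 in wild type and −1.96 in Ser585Gly). Xpnpep2 was at 0.05 in wild type and −1.14 in Ser585Gly, Ighm at −1.38 and 0.05, and Tln2 at −0.875 and 0.535.

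The same test of the difference between responses picked 5 gene lists (camera). The mean interaction was 0.13 for the cell cycle, 0.22 for ribosome biogenesis, −0.13 for the amino acid response, 0.23 for cholesterol and fatty acid synthesis and 0.14 for chaperones. None of the 5 passed with an estimated correlation (adjusted p = 0.0677 to 0.652).

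Cholesterol and fatty acid synthesis genes were higher in Ser585Gly at 12 h, with a median log2 ratio of 0.61 over 28 genes, of which 16 passed (camera adjusted p = 8.39e-21; adjusted p = 0.0663 with an estimated correlation). For a bias that follows spot brightness, the median lay at percentile 100 of 10000 random lists of matched brightness, whose highest median was 0.16. Loess had already removed an average trend with brightness on each array. The comparison shows only that other genes of like brightness were not shifted as far. For a dye bias, opposite signs were predicted, and the medians on the arrays of the dye-swap pair were 0.61 and 0.55 once turned the same way. A dye bias common to both arrays cancels between them and is taken up by the dye term of the fit. This comparison therefore cannot decide on a dye bias. It shows only that both orientations carried the difference. A difference that comes with the mutation is a candidate explanation, held as a hypothesis since it was found and tested on the same arrays. A difference between the 2 cell populations that arose apart from the mutation stays open and untested, because each receptor form was measured in 1 population.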

How the results depend on the processing

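The limit to probes at their nearest spot, names in the deposited order, and the correlation with single arrays left out were chosen only after the result was seen. No named gene past the threshold reversed under the alternatives that kept the recovered names. With names in the deposited order, 165 of 334 such results had the opposite sign, and 9 passed the threshold the same way and 9 the opposite way. With pairs averaged, 76 of 100 named genes past the threshold kept their call for time in wild type, 73 of 92 for time in Ser585Gly, 43 of 82 for the mutation at 0 h, 35 of 55 at 12 h and 0 of 9 for the interaction. The counts below are for time in wild type, time in Ser585Gly, mutation at 0 h, mutation at 12 h and interaction, in that order, where all 5 are given (2062, 2273, 887, 373 and 12 in the fit reported). Pairs averaged gave 1062, 1335, 275, 151 and 0, and direct arrays alone gave 884, 1145, 226, 158 and 0 (limma), with fewer values per estimate by construction. With direct arrays alone 761 interaction probes had an unadjusted p under 0.05, fewer than the share of 0.05 that no interaction would give. Print-tip loess gave 4084, 4282, 2043, 991 and 49, the deposited log2 values gave 4164, 4224, 2540, 2193 and 90, and the dye-swap pair as a random block 4184, 4311, 3387, 1130 and 35. At 0 h, median centring gave 544 and no dye term 509; at 12 h, scaling between arrays gave 735. The interaction gave 20 without background correction, 20 with limma's rule of subtraction with a floor, 7 with offset 10, 1 with scaling and 6 with no dye term. Apart from this property of the random block, the cause was not tested for these. Single arrays left out gave 411 to 3303, 276 to 3429, 108 to 636, 67 to 625 and 0 to 5. The correlation of the time effects was 0.557 to 0.696 with single arrays left out and 0.683 to 0.810 over the other settings run. Of 130 list tests 40 passed, 32 to 43 with single arrays left out, 35 with probes at their nearest spot, and 0 both with an estimated correlation and with names in the deposited order (camera). The test with an estimated correlation also had fewer degrees of freedom, so its 0 does not rest on correlation alone. The p with an estimated correlation was the highest over a list's alternatives with the recovered names, except for ribosomal proteins over time in wild type (0.188 with the deposited table) and mast cell markers at 0 h (0.474 without the dimmest probes). Print-tip loess, scaling and the deposited log2 values ended the call of T cell effectors at 0 h (adjusted p = 0.318, 0.133 and 0.292), and median centring that of ribosome biogenesis at 12 h (0.0559). Other lists lost calls to such settings too, for example FoxO targets at 12 h and mast cell markers at 0 h without background correction (camera adjusted p = 0.0568 and 0.101). Aquantile left the ratios as they were and so tests nothing, and leaving out spots with a negative flag was not run because the files hold no flags. List tests with a random block or a trended prior were run on the t-values of the fit (cameraPR in limma). No paired analysis was possible because replicate numbers only name dye orientations. Cy3 signal at 6.38 times its background on 1 array limits what dim spots can show; without the dimmest 30% of probes the interaction count was 16.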

Other observations

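The tests of the print order and of B cells and myeloid cells in this part, with the brightness limit on their markers, and the overlap from direct arrays, were chosen only after the result was seen.

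Differences between the populations were shared between the times. The direct log2 ratios of Ser585Gly over wild type at 0 h and 12 h had a Pearson correlation of 0.424 and a Spearman correlation of 0.362 across 21766 probes, which are not independent replicates, against −0.0142 to 0.0114 for Pearson in 20 simulated data sets with no effect. Probes that passed at both times numbered 135 higher and 136 lower, with 0 in opposite directions (limma), from estimates that share arrays. From direct arrays alone, which are not shared, 34 were higher at both times, against 0.400 for independent sets, and 45 lower, against 0.417, with 0 in opposite directions. The estimate of spread per probe is still shared, so the values for independent sets are low references. Among the higher at 0 h were Cdkn2a, a locus of cell cycle inhibitors (1.64), Ccl11, the eosinophil chemokine eotaxin (1.74), Esm1, a secreted proteoglycan (1.71), and Tnfrsf9, a costimulatory receptor (1.07 on 1 of 2 probes). Among the higher at 12 h was Shh, which encodes a hedgehog ligand (1.86). Chit1, a chitinase of macrophages, was lower at both times (−1.97 and −1.71), and Lilr4b, an immunoglobulin-like receptor of leukocytes, was at −2.46 at 12 h. Irf8 was at 0.23 (adjusted p = 0.175) over time in wild type and rose by 1.04 in Ser585Gly, with an interaction of 0.81 that did not pass (adjusted p = 0.0696). Anxa2 fell over time in both populations, by 0.88 in wild type and 1.38 in Ser585Gly. Il10, an anti-inflammatory cytokine, rose in both populations (1.61 in wild type and 1.17 in Ser585Gly).

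Of MHC class II, 4 genes put together after they were seen, and not tested as a group, had a mean log2 ratio of 1.45 at 0 h and 1.22 at 12 h in Ser585Gly against wild type. B cells in the culture would raise their other markers, but over the 11 of 15 other B cell markers brighter than the median of silent gene families the third quartile was 0.012 at 0 h, with Igkc at −0.48, Fcer2a at −0.04 and Cd22 at −0.03, although Ms4a1 was at 0.48, Blk at 0.09 and Cr2 at 0.05. Myeloid cells would raise theirs, but over 20 of 25 myeloid markers the third quartile was 0.18 (0.25 over all 25), with Lyz2 at −0.34, C1qa at 0.03 and Ctsg at −2.07, although Fcgr3 was at 0.87, Cd68 at 0.51, and Marco and Fcer1g at 0.41. Both quartiles lay under 0.73, which is 0.5 times the class II mean, a limit set after the result was seen. Most of the listed markers thus did not rise as class II did. The median brightness percentile was 96.0 for class II, but 44.8 for the B cell markers and 53.1 for the myeloid markers. A single myeloid type need not carry most of the listed markers. The comparison therefore cannot exclude either cell type, and a myeloid type with few of the listed markers stays open. A change that comes with the receptor form may account for the pattern, as a hypothesis, and a difference between the populations that arose apart from it stays open and untested.

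In the deposited order, probes of the same gene did not move together, and 2 explanations were tested. With 24 pins in place of 48, the rank correlation of the time effect between the probes of 1 gene was 0.311 over 903 genes (permutation p = 0.000999, the smallest that 1000 permutations can give), against −0.057 in the deposited order and 0.033 and 0.042 in other 24-pin orders. Too little signal on the spots would leave such correlations near 0 in every order, but that of the mutation effect was 0.277 in the recovered order. This is consistent with a print by 24 pins, and 9 of 338 named results past the threshold passed the same way under the deposited names. The print records were not used here, and no biological explanation was tested.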
